A study of Daucus carota and Daucus carota
Rhizophagus irregularis with 16 samples.

How the data were processed

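RNA from fine roots of carrot was sequenced in 16 libraries, 4 in each combination of watering (regular or diminishing) and inoculation (with or without Rhizophagus irregularis). Per the labels' protocols, total RNA was treated with DNase, and libraries were prepared by a commercial provider and sequenced on an Illumina NovaSeq instrument. Per the submitters' processing notes, the tools were FastQC 0.11.5, kallisto 0.42.3, sleuth and R 3.5.2. The genome builds and annotations behind the gene models are not given in the sources used here. The deposited tables hold, per the file headers, the estimated counts and the TPM that kallisto assigns to each gene model, with its length and effective length. TPM in the deposited files are scaled over both organisms together. The sources used here do not state whether reads were trimmed, nor whether the libraries kept strand.

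Each table held 32118 carrot gene models and 26183 fungal gene models. Estimated counts need not be whole, since kallisto divides reads between models that share sequence: 7.30% of values above 0 were not whole numbers. Counts were rounded to whole numbers before testing, and loci that share reads with near-identical copies are therefore uncertain. The 9 split carrot models of 4 loci were summed, which left 32113 carrot loci. All carrot lengths were multiples of 3, so they are coding lengths, against 59.5% of fungal lengths. In uninoculated watered replicate 4 the table repeated 22074 fungal rows with identical values and held 1 row with a shortened identifier. Each model was used 1 time and the shortened row left out.

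Gene names were not assigned. The identifiers come without descriptions, and 0 carrot and 0 fungal identifiers matched the reference table, which belongs to carrot assembly DH1 v3.0. The lists of gene groups fixed before the data were examined could therefore not be applied, nor could the part of the rule for named genes that needs a description. What remained of that rule named, per contrast, the 2 largest rises and the 2 largest falls among models past the threshold whose log2 CPM ranges in both groups do not overlap, with a mean of at least 5 CPM in the higher group. For the interaction no model qualified.

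Carrot and fungal models were analysed separately, each scaled to its own organism's counts. Carrot loci were tested with edgeR 4.0.16 (quasi-likelihood F-test, robust, TMM factors, filterByExpr by group) in R 4.3.3, in 1 model of the 4 groups with 12 residual degrees of freedom, which tested 23110 loci. The contrasts were drought without the fungus, drought with the fungus, the fungus in watered roots, the fungus under drought, and the interaction. Fungal models were tested in the 8 inoculated libraries with 6 residual degrees of freedom, which tested 8439 models. Calls are at a Benjamini-Hochberg adjusted p under 0.05 within each contrast. Log2 fold changes are edgeR's, with a prior count, and CPM values of single models use the TMM-scaled carrot or fungal library size. The SE of a log2 fold change is its absolute value over the square root of the F statistic. It is approximate, since edgeR's test gives no standard error. Summed CPM of a group of loci use the carrot counts of the library without TMM factors. Where a group had 0 counts, the fold is a bound against a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio has a 95% counting interval. Floors and intervals cover counting error only. At these depths, 3 counts over a group of 4 libraries corresponded to 0.0415 to 0.0501 CPM in carrot and to 1.20 CPM of fungal counts in inoculated watered libraries.

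The fungal share of a library was the percent of its counts on fungal models, compared between groups with an exact permutation test of the difference in means (two-sided, smallest possible p = 0.0286 for 4 against 4). Overlaps of calls are given beside n1 × n2 / N for independent lists. Permutation tests and figures used Python 3.11.15 with scipy 1.17.1.

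The models were tested on simulated counts drawn from the means, dispersions and library sizes of the real libraries. Each gene model had the same dispersion in all groups. In the real libraries the median variance of log2 CPM was 1.35 times as high in inoculated as in uninoculated groups. The simulated recovery and false calls therefore do not cover groups of unequal spread. In each simulation 67 models were changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold, and all others were left unchanged. The carrot comparison of 4 against 4 tested 22792 simulated loci. Where many more loci change, as under drought, the adjusted threshold is less strict. The recovery given here can therefore be too low for the drought comparisons. For a carrot comparison of 4 against 4, the test recovered 1.49%, 23.9% and 59.1% of loci changed 1.5-fold, 2-fold and 4-fold, with 2 false calls among 58. For the interaction it recovered 0%, 4.48% and 51.5%, with 0 false calls among 37. For the fungus it recovered 2.99%, 31.3% and 81.8%, with 7 false calls among 84. All 24 pairs of replicates within a group differed by more than sampling noise (chi-square per degree of freedom from 25.0 to 96.2), so no library was treated as a duplicate.

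Alternatives fixed before the data were examined were DESeq2 1.42.0, DESeq2 size factors in edgeR, library totals, other filters on low counts, limma 3.58.1 on log2(TPM + 1), a minimum fold of 2, TMM over both organisms, a fit of only the groups compared, a replicate block, carrot counts as the library size for the fungus, omission of background fungal models, and leaving out each library in turn.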

Results

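Gene expression was measured in fine roots of carrot (Daucus carota, cultivar Napoli) grown with or without the arbuscular mycorrhizal fungus Rhizophagus irregularis, an obligate symbiont that lives inside root tissue and exchanges mineral nutrients for plant carbon. Plants were kept regularly watered or received less and less water during the last 10 days of growth, after 50 days under regular watering. The 16 libraries fell into 4 groups of 4: uninoculated and watered, uninoculated and droughted, inoculated and watered, and inoculated and droughted. Because each library was quantified against gene models of both organisms, carrot and fungal transcripts were read from the same RNA. The series asked how plant and fungus each respond to drought. Total estimated counts per library ranged from 13367657 to 19277406. Group means were 15564000 ± 964200 (SD, n = 4) in uninoculated watered roots, 17809000 ± 1581900 in uninoculated droughted roots, 15750000 ± 1773400 in inoculated watered roots and 16741000 ± 2050400 in inoculated droughted roots. The deposited identifiers pair with no gene names, so the results are given as groups of loci, with at most 2 rising and 2 falling identifiers per comparison. P-values measure the spread between the sequenced samples, since the labels do not say that replicates of a group were separate plants.

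Watering and inoculation each separated the carrot libraries. On the first principal component, which held 33.9% of the variance, the 8 watered libraries lay between -118 and -55.2 and the 8 droughted libraries between 57.8 and 93.0. On the second component, with 20.1%, uninoculated libraries lay between -70.6 and -43.3 and inoculated libraries between 30.9 and 77.3.

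**Figure D1:**
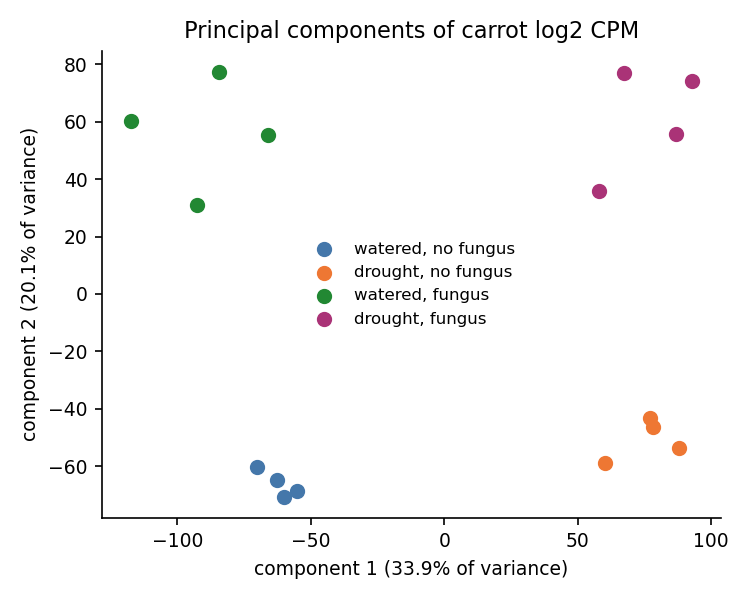
Principal components of log2 CPM (counts scaled to library size) of the tested carrot loci, with 1 point per library coloured by group. Component 1 (33.9% of the variance) parts watered from droughted libraries, and component 2 (20.1%) parts uninoculated from inoculated libraries.

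The first comparison asked how roots without the fungus respond to drought. Of 23110 tested carrot loci, 2025 rose and 2789 fell in droughted roots, together 20.8% of those tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The 2025 rising loci held 6.60 ± 0.339% (SD, n = 4) of carrot counts in watered roots and 16 ± 0.714% in droughted roots. The 2789 falling loci went from 21.5 ± 0.713% to 10.0 ± 0.487% of carrot counts. The median change was 1.21 on the log2 scale among rising loci and -1.34 among falling loci, and 1235 loci rose and 1805 fell by at least 2-fold.

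Among single loci without the fungus, DCAR_006562 went from 0.0976 ± 0.11 CPM (SD, n = 4) in watered roots to 8.25 ± 8.62 CPM in droughted roots, a log2 fold change of 6.28 ± 1.09 (SE, edgeR adjusted p = 0.0011). It was 7.31 without watered replicate 1 and 5.30 without droughted replicate 4. DCAR_012491 rose from 0.0627 ± 0.0724 to 5.36 ± 4.15 CPM, or to 3.46 CPM without droughted replicate 3. DCAR_020380 fell from 50.3 ± 58.7 to 0.0268 ± 0.0309 CPM, with 3136 counts in the watered group and 2 in the droughted group, a ratio of 1860 (95% counting interval 513 to 15300). Its watered mean rested largely on replicate 1, at 138 CPM against 13.4 to 26.4 CPM in the other 3 libraries, and without it the watered mean was 21.1 CPM. DCAR_029380 fell from 10.4 ± 7.89 CPM to 0 counts in the droughted group, which is at least 251-fold lower against a floor of 3 counts over the group, or 161-fold without watered replicate 4.

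In inoculated roots, 3193 of the same 23110 loci rose under drought and 3699 fell, together 29.8%. This count exceeded that without the fungus mainly in the model of all 16 libraries: with only the 2 groups of each comparison in the fit, 5230 loci passed with the fungus and 4795 without it. The 3193 rising loci held 12.7 ± 1.24% (SD, n = 4) of carrot counts in watered roots and 26.1 ± 1.14% in droughted roots, and the 3699 falling loci went from 26.5 ± 2.04% to 11.4 ± 1.27%. The median log2 change was 0.97 among rising loci and -1.43 among falling loci, with 1516 rises and 2504 falls of at least 2-fold.

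DCAR_013622 was among the loci with the largest rises in inoculated roots, from 0.0926 ± 0.185 CPM (SD, n = 4) when watered to 19.7 ± 16.5 CPM under drought (log2 fold change 7.72 ± 1.42 SE, edgeR adjusted p = 0.00112). All 5 watered counts were in replicate 4, without which the locus was at least 305-fold higher under drought against 3 counts over the other 3 watered libraries. The droughted mean was 11.9 CPM without droughted replicate 4. DCAR_015339 rose from 2 counts over the watered group to 332 over the droughted group, a ratio of 160 (95% counting interval 44.1 to 1330), with 1.21 CPM in droughted replicate 1 and 6.45 to 7.48 CPM in the other 3. Both watered counts were in replicate 4, and without it the locus was at least 85.7-fold higher. DCAR_030250 fell from 21.8 ± 16.8 CPM to 0 counts, at least 451-fold lower against 3 counts over the group. DCAR_020380 fell here too, from 79.96 ± 45.7 to 0.0433 ± 0.0552 CPM, a ratio of 1660 on 4822 and 3 counts (95% counting interval 569 to 8070). Without droughted replicate 3 its droughted mean was 0.0192 CPM and its log2 fold change went from -10.48 to -11.38.

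**Figure D2:**
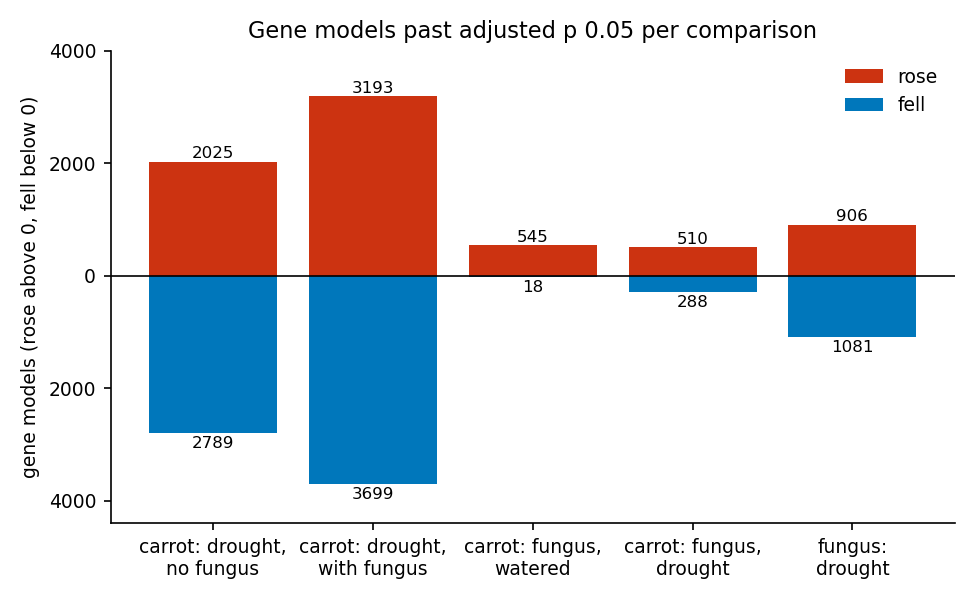
Number of gene models that rose (bars above 0) and fell (bars below 0) past an adjusted p of 0.05 in each comparison, with 4 libraries against 4 in each. Drought moved 2025 up and 2789 down in carrot without the fungus, and 3193 up and 3699 down with it, against 545 up and 18 down for the fungus in watered roots.

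Most loci called for drought in uninoculated roots were also called in inoculated roots. Both comparisons share no library, but take their spread from the same fit of all 16 libraries, so the lists of calls are not fully independent. Of the 2025 loci that rose without the fungus, 1442 also rose with it (71.2%), where independent lists of these sizes would share 280. Of the 2789 that fell without the fungus, 2192 also fell with it (78.6%), against 446 for independent lists. Across all 23110 loci, the log2 changes under drought correlated between inoculated and uninoculated roots with a Pearson r of 0.716 and a Spearman rho of 0.721. This correlation is across genes, which are not independent replicates. In only 8 loci were the calls opposite: 5 rose without the fungus and fell with it, and 3 did the reverse.

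No locus had a drought response that differed between inoculated and uninoculated roots by the edgeR quasi-likelihood test of the interaction (0 of 23110, smallest adjusted p = 0.0714). At an unadjusted p under 0.05 there were 1570 loci, where 1156 would be given by independent tests without any effect. DESeq2 called 135 loci, 41 with a more positive and 94 with a more negative drought response in inoculated roots, and limma on log2(TPM + 1) called 54. Counts were simulated at this depth with few loci changed and the same spread in all groups. In them the interaction test recovered 51.5% of loci changed 4-fold and 4.48% of those changed 2-fold. Most differences of that smaller size would thus be missed if few loci differed.

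**Figure D3:**
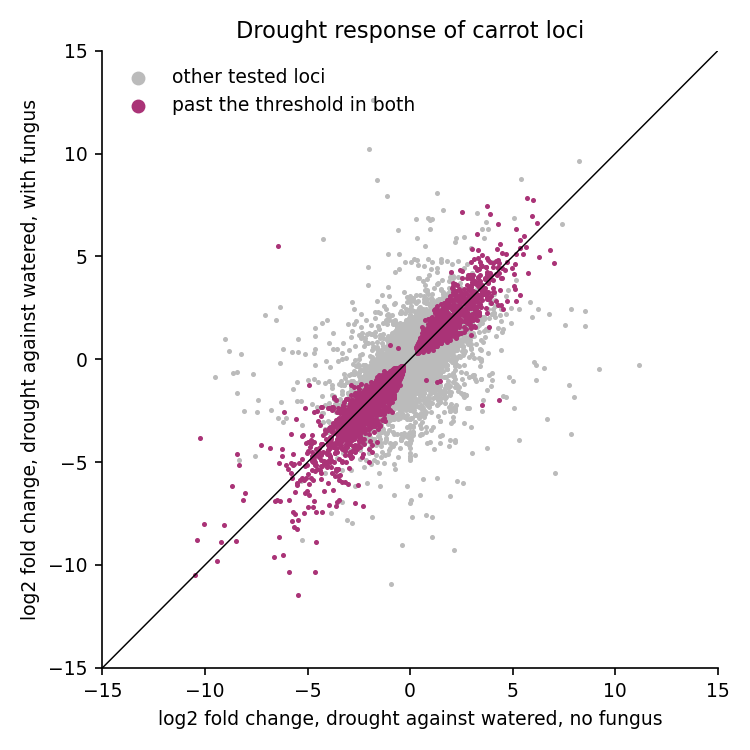
Log2 fold change of each tested carrot locus between droughted and watered roots, without the fungus on the horizontal axis and with it on the vertical axis. Points coloured purple passed the threshold in both comparisons, and the line marks equal change. Pearson's r across the 23110 loci was 0.716.

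The response of watered roots to the fungus was smaller in number and nearly all upward. With the fungus, 545 of 23110 loci rose and 18 fell, 2.44% of those tested. The 18 falls became 10, 8 and 7 without uninoculated replicates 3 and 4 and inoculated replicate 1, in turn, and 50 in DESeq2. The 545 rising loci held 0.178 ± 0.0167% (SD, n = 4) of carrot counts in uninoculated roots and 1.45 ± 0.520% in inoculated roots. Their changes were large: 470 rose at least 4-fold, and the median log2 change was 5.33 with loci without counts in uninoculated roots set at their bound. In 101 of the 545 loci the uninoculated watered group had no count.

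DCAR_025180 had 0 counts in uninoculated watered roots and 172 ± 177 CPM (SD, n = 4) in inoculated watered roots, at least 3500-fold higher against 3 counts over the group (edgeR adjusted p = 0.000178). Inoculated replicate 2 held 428 CPM against 45.8 to 152 in the others, and without it the bound was 1760-fold. DCAR_000887 had 0 counts and 114 ± 32.4 CPM, at least 2330-fold higher (edgeR adjusted p = 4.66e-05). Of the 18 falling loci, DCAR_021204 fell from 8.72 ± 2.71 to 2.33 ± 0.516 CPM (log2 fold change -1.90 ± 0.363 SE, edgeR adjusted p = 0.00583). DCAR_011541 fell from 9.25 ± 3.54 to 2.48 ± 0.431 CPM (edgeR adjusted p = 0.0426), a call lost when any 1 of the 8 libraries was left out, with an edgeR, DESeq2 or limma adjusted p of 0.00169 to 0.191 over the 17 alternatives tried.

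With the fungus 510 loci rose and 288 fell in droughted roots, 3.45% of those tested. The 510 rising loci went from 0.761 ± 0.0486% (SD, n = 4) of carrot counts to 1.92 ± 0.338%, and the 288 falling loci from 2.14 ± 0.537% to 0.865 ± 0.0731%. The median log2 change was 4.02 among rising loci, with loci at 0 set at their bound, and -1.41 among falling loci. The count of 798 depended on single libraries and on the tool. It was 515 (147 falls) without uninoculated droughted replicate 1, 514 (146 falls) without replicate 2 of that group and 417 (84 falls) without inoculated droughted replicate 2, while DESeq2 called 1557 (721 falls), limma 451 (172 falls) and a fit of these 2 groups alone 459 (153 falls).

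DCAR_016830 had 0 counts in uninoculated droughted roots and 140 ± 110 CPM (SD, n = 4) in inoculated droughted roots, at least 3370-fold higher against 3 counts over the group (edgeR adjusted p = 0.00113). DCAR_012201 had 0 counts and 110 ± 87.8 CPM, at least 2640-fold higher. DCAR_022022 fell from 31.7 ± 39.1 to 1.38 ± 1.23 CPM and DCAR_014164 from 42.1 ± 9.32 to 2.62 ± 1.33 CPM, with log2 fold changes of -4.53 ± 1.05 and -3.99 ± 0.957 (SE, edgeR adjusted p = 0.0256 and 0.0311). DCAR_022022 lost its call without uninoculated replicate 2 or inoculated replicates 1, 2 or 3, or with only the 2 groups in the fit, and its log2 fold change was -3.24 without uninoculated replicate 2 and -5.15 without inoculated replicate 4. DCAR_014164 lost its call in limma and without any 1 library other than uninoculated replicate 3. Over the 17 alternatives tried, their adjusted p in edgeR, DESeq2 or limma ranged from 0.00252 to 0.125 and from 0.000357 to 0.104.

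The rising loci were largely shared between watered and droughted roots, in comparisons that share no library but take their spread from the same fit. Of the 545 loci that rose with the fungus in watered roots, 342 also rose under drought, where independent lists would share 12. Of the 18 that fell in watered roots, 5 also fell under drought, against 0.224. Across all loci the fungus responses in watered and droughted roots correlated with a Pearson r of 0.676 and a Spearman rho of 0.268, again across genes. Whether the 288 falls under drought differed from the change in watered roots is covered by the interaction test, which is the same for both factors and called 0 loci in edgeR, 135 in DESeq2 and 54 in limma.

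Averaged over both waterings, 800 loci rose with the fungus and 320 fell. Of those 800, 327 (40.9%) fell and 65 (8.12%) rose under drought in inoculated roots, where 16% of all loci fell and 13.8% rose. In uninoculated roots 153 (19.1%) of the 800 fell and 47 (5.88%) rose under drought, where 12.1% of all loci fell and 8.76% rose. Of the 320, 107 (33.4%) fell and 48 (15%) rose under drought in inoculated roots, and 54 (16.9%) fell and 87 (27.2%) rose in uninoculated roots, where 12.1% of all loci fell and 8.76% rose. The 800 were chosen as higher in inoculated roots, so their counts were lower in uninoculated roots, where a fall is harder to call. The same choice set the 320 lower in inoculated roots. The shares in inoculated and uninoculated roots therefore do not compare the size of the drought response. They were not tested against each other.

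A group of 65 carrot loci had counts in inoculated roots alone, with at most 3 counts summed over the 8 uninoculated libraries and at least 10 in each of the 8 inoculated libraries. No locus met the reverse criterion. The 65 loci summed to 0.561 ± 0.261 CPM (SD, n = 4) in uninoculated watered roots, 0.360 ± 0.202 in uninoculated droughted roots, 1600 ± 798 in inoculated watered roots and 1180 ± 791 in inoculated droughted roots. The difference between the inoculated groups was within the spread of replicates (two-sided exact permutation p = 0.457). Per 1000 fungal counts, the same loci gave 39.8 ± 11.3 counts in watered roots, with libraries from 26.7 to 50.0, and 14.1 ± 2.86 in droughted roots, from 11.3 to 17.8 (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 allows). This ratio was examined only after the data had been seen. Taken singly, 22 of the 65 fell and 4 rose under drought in inoculated roots, and 39 did not pass the threshold.

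**Figure D4:**
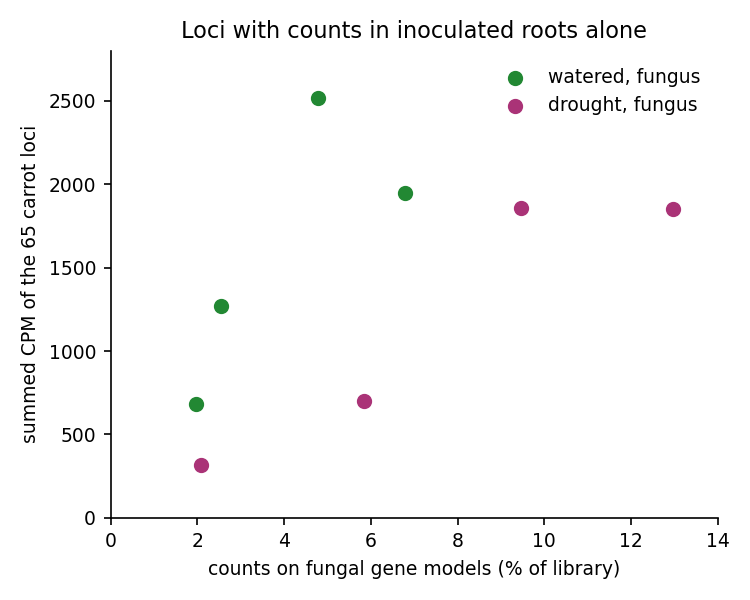
Summed CPM of the 65 carrot loci with counts in inoculated roots alone (vertical axis) against the percent of each library's counts on fungal models (horizontal axis), with 1 point per inoculated library. The 4 droughted libraries lay at 11.3 to 17.8 counts of these loci per 1000 fungal counts and the 4 watered libraries at 26.7 to 50.0.

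The fungal share of counts measured how much fungal RNA the roots held relative to carrot RNA. Fungal gene models took 4.02 ± 2.21% (SD, n = 4) of counts in inoculated watered roots and 7.59 ± 4.68% in inoculated droughted roots. Single libraries ranged from 1.96% (95% Wilson interval 1.95 to 1.97) to 6.80% when watered and from 2.09% to 13% under drought, so the spread between libraries far exceeded counting error. The ranges of droughted and watered roots overlapped, and their difference of 3.56 percentage points did not pass the test (two-sided exact permutation p = 0.257). The background in uninoculated libraries was 0.584 ± 0.119% when watered and 0.475 ± 0.0745% under drought, and both inoculated groups exceeded it (two-sided exact permutation p = 0.0286 for each watering).

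**Figure D5:**
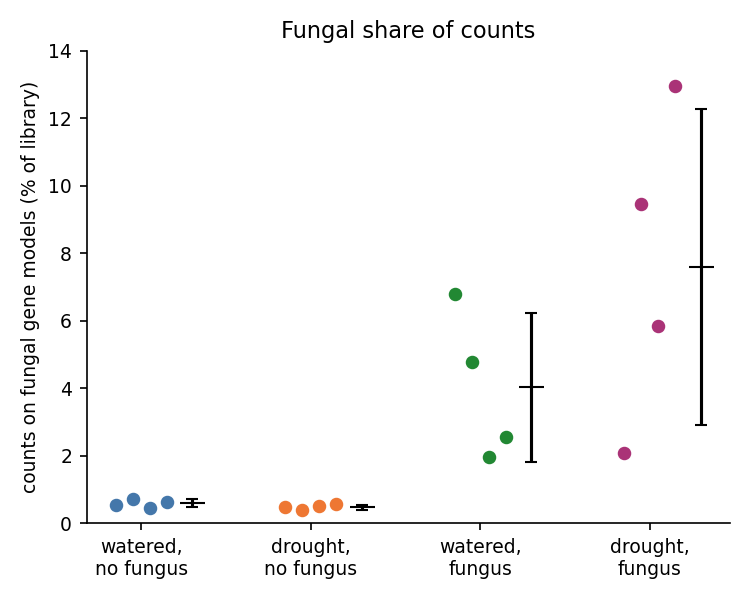
Percent of each library's counts on fungal gene models, with 1 point per library and bars for the group mean and SD (n = 4). Inoculated watered libraries ranged from 1.96% to 6.80% and inoculated droughted libraries from 2.09% to 13%, against 0.380% to 0.720% in uninoculated libraries.

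The fungus itself changed its transcript profile under drought. Among 8439 tested fungal models, 906 rose and 1081 fell relative to TMM-scaled fungal counts, together 23.5% (edgeR quasi-likelihood test, adjusted p under 0.05). Relative to total fungal counts, 964 rose and 748 fell. The 906 rising models went from 6.21 ± 1.11% (SD, n = 4) to 22.7 ± 3.04% of fungal counts, and the 1081 falling models from 24.2 ± 1.77% to 10.6 ± 1.67%. Median log2 changes were 1.41 and -1.49. The balance of directions depended on the scaling: 45.6% of calls were rises with trimmed-mean scaling and 56.3% with library totals alone, which shift the median of all models by 0.13 on the log2 scale. In limma on log2(TPM + 1), which also changes the test, the unit and the filter, 81.6% of 743 calls were rises. Scaled to carrot counts, which also takes in the differing amount of fungal RNA per library, 249 models were called, with 93.2% rises.

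Some fungal models had counts in 1 watering alone. Model Rhiir2_1|1639109 had 0 counts in inoculated watered roots and 981 ± 719 CPM of fungal counts (SD, n = 4) under drought, at least 814-fold higher against 3 counts over the group (edgeR adjusted p = 0.00427), or 532-fold without droughted replicate 1. Model Rhiir2_1|1498325 had 0 counts when watered and 612 ± 96.5 CPM under drought, at least 508-fold higher (edgeR adjusted p = 4.55e-10). Models Rhiir2_1|1766518 and Rhiir2_1|1859549 fell from 37.8 ± 19.6 and 34.1 ± 6.52 CPM to 0 counts under drought, at least 65-fold and 58.6-fold lower. In all, 23 of the 906 rising models had no count in the watered group and 2 of the 1081 falling models had none in the droughted group.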

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

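The tests of the fungal counts in uninoculated libraries were chosen after those counts had been seen. Uninoculated libraries held counts on fungal models, 87726 per library on average (63006 to 119119), in libraries that enter no test of single fungal models. The 45 fungal models with a mean of at least 1 CPM of all counts in uninoculated libraries were taken as background. Relative to carrot counts, these models were 1.07 times as high in inoculated as in uninoculated libraries. The fungal share of counts differed by 6.89 times in watered and 16 times in droughted roots. The other fungal models reached 0.0589% of their inoculated level in uninoculated libraries. Because models with more counts there had been set aside as background, this low level alone does not decide whether fungus grew in the uninoculated pots. A candidate explanation is that carrot reads are assigned to these 45 models, which held 99.4% of fungal counts in uninoculated watered libraries, 18.7% in inoculated watered libraries and 10.4% in inoculated droughted libraries. Sequences of the models were not used here, so shared sequence itself was not tested.

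A library far from the other 3 of its group was found in 5 of the 58 groups of values examined. Chance would give about 2.9 for independent, normally distributed values. Counts near 0 of loci named for large changes are not such values, so the 2.9 does not judge the 5. Uninoculated droughted replicate 4 had a gene length minus effective length of 229.7 nucleotides, against 273.7 to 277.8 in the rest of its group. DCAR_020380 stood at 137.9 CPM in uninoculated watered replicate 1, against 13.4 to 26.4 CPM. DCAR_015339 stood at 1.21 CPM in inoculated droughted replicate 1, against 6.45 to 7.48 CPM. In inoculated watered replicate 4, DCAR_013622 stood at 0.371 CPM and DCAR_015339 at 0.148 CPM, against 0 counts of either in the other 3 libraries.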

How the results depend on the processing

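The results on induced loci per fungal count, the thinned fungal counts and the fungal share without background models were chosen after seeing the data. Of the 116 alternatives to the 6 counts of calls, 101 stayed within 1.5 times the main count. With at least a 2-fold change required, drought calls were 3040 without and 4020 with the fungus, since fewer loci qualify. DESeq2 called 1557 loci for the fungus under drought and 135 for the interaction. Limma on log2(TPM + 1) called 451, 54 and, in the fungus, 743. The fungus under drought gave 459 calls with 2 groups in the fit, and 417 to 766 with 1 library left out; the interaction gave 0 to 3. Fungal drought calls were 249 with carrot counts as library size and 1216 without background models and thinned to 228370 counts per library, which leaves fewer models to test; without background models alone they were 2012. Other causes were not tested. The drought correlation was 0.844 and the fungus correlation 0.785 over loci of at least 10 CPM, and 0.650 to 0.710 and 0.618 to 0.659 with 1 library left out. Induced loci per fungal count kept their direction, at 0.319 to 0.387 of the watered level with 1 library left out, where 3 against 4 cannot reach an exact permutation p below 0.0571. The fungal share difference was 1.77 to 5.40 percentage points with 1 library left out, 1.47 in TPM and 3.69 without background models, never past the threshold. Named models kept their direction in all 340 alternatives that tested them and lost the call in 24, all of them DCAR_011541, DCAR_014164 and DCAR_022022. A further 4 gave no value: DCAR_029380 in limma, Rhiir2_1|1859549 with carrot counts as library size, and Rhiir2_1|1766518 and Rhiir2_1|1859549 when thinned. Replicate numbers did not pair the samples: deviations of same-numbered libraries correlated over 0.1 in 3 of 24 pairs, against 12 of 72 other pairs, and 6 of 16 libraries were closest to their own number. With the replicate block, calls were 4193, 6313, 498, 577, 0 and 1725, and the fungal share difference 3.56. It gave 178 falls for the fungus under drought, and adjusted p (edgeR) of 0.0579, 0.06 and 0.0791 for DCAR_011541, DCAR_014164 and DCAR_022022. The gene lists and their set tests were not run, since no model has a name. Depth was varied only in the thinned fungal counts. At the depth of the real libraries, with equal spread in all groups and few loci changed, the simulated carrot test recovered 23.9% of 2-fold changes. The part due to depth was not tested.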

Other observations

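The splits for the interaction, the comparison of induced loci at an equal fungal share, the test of the difference per fungal count, the test of a shared spread and the settings of the extra drought response were chosen after the result was seen. Loci that rose with the fungus in watered roots often carried consecutive locus numbers. Among the 545 loci there were 52 pairs of consecutive numbers, where 1000 random draws of as many tested loci gave 9.96 on average and 21 at most. In all, 94 of the loci stood in runs of 2 or more, 7 runs had 3 or more members and the longest had 5. One hypothesis is that neighbouring copies may rise together, but reads shared between similar neighbouring loci could give the same 52 pairs, and neither positions nor sequences of the loci were used here.

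A few loci were seen in 1 watering alone. By the criterion used for the 65 loci, with at most 3 counts summed over 8 libraries and at least 10 counts in each of the other 8, 2 carrot loci were seen in droughted roots alone and 4 in watered roots alone.

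The 65 loci seen in inoculated roots alone gave fewer counts per fungal count under drought, 14.1 ± 2.86 against 39.8 ± 11.3 per 1000 (SD, n = 4, two-sided exact permutation p = 0.0286). Fungal reads assigned to carrot loci at random would follow the fungal models. The median log2 change per fungal count was instead -2.34 over the 65 loci, with 57 of them below 0, against -0.38 to 0.35 in 10000 random sets of fungal models. This covers only reads drawn at random across fungal models, and reads from a few similar models were not tested. Without the 45 background models the droughted level was 0.322 of the watered level, so these do not make the difference. At an equal fungal share, with a slope of 0.84, the loci were still 2.65-fold lower (log2 difference -1.41, two-sided exact permutation p = 0.0857). A rise less than in proportion to the amount of fungus is therefore left open as the cause. A lower response of the root per amount of fungus under drought is a hypothesis for the pattern that these 8 libraries do not separate from such a rise.

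Drought called 6892 loci with the fungus and 4814 without it. A smaller spread between inoculated libraries would give more calls, but the median variance of log2 CPM was 1.35 times as high in them. With only the 2 groups of each comparison in the fit, 5230 and 4795 loci were called and 20.9% of the excess was kept, so the spread shared by all 4 groups is a candidate explanation for most of it. The mean change in the direction of the average response, over 9377 loci, was 1.27 with and 1.08 without the fungus on the log2 scale, and the extra of 0.185 stayed at 0.123 or more with each of the 16 libraries left out. An exact permutation over 4900 assignments of inoculation, drawn separately in each watering, gave a two-sided p of 0.109. Most of these assignments also take in the response to the fungus itself. This p therefore does not decide whether the drought response is larger in inoculated roots, with 4 libraries per group.

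Other splits of the 8 libraries of a comparison into 4 and 4 gave as many calls in 1 of 35 splits, the real one, for each of 5 comparisons. For drought without the fungus the real split gave 4814 calls and the highest other 1. For drought with the fungus these were 6892 and 1, for the fungus in watered roots 563 and 11, for the fungus under drought 798 and 599, and for drought in the fungus 1987 and 1. The real split came first each time by these calls, but 1 of 35 is the smallest share these splits allow. By loci at an unadjusted p under 0.05, it did not come first for the carrot response to the fungus. In watered roots it gave 1828 such loci, against 2368 in another split. Under drought it gave 3651, against 3926 and 4190 in other splits. A real difference also widens the spread of splits that mix both groups, which lowers their calls. The rank alone therefore does not exclude chance. It is least firm for the fungus under drought, where another split gave 599 calls. In separate fits with 1 library left out, the real grouping gave as few as 417 calls. The split with 599 calls set uninoculated replicates 1 and 3 and inoculated replicates 1 and 2 against the other droughted libraries, which points to a structure among the droughted samples that the groups do not name. For the interaction, 50 groupings were counted: the real one and reassignments that exchanged as many libraries in each watering. Of these 50, 8 gave 1570 or more loci at an unadjusted p under 0.05, the real one among them, so chance cannot be excluded. The highest gave 4169 such loci and 505 calls past the threshold, against 0 calls in the real grouping.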
